A study of Mus musculus with 12 samples.

How the data were processed

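Gene expression was measured on 12 whole-transcript mouse gene arrays, 4 for each of 3 groups. Each array held RNA of donor CD4+ T cells that had divided at least 2 times in a host mouse. Donor spleen cells of C57Bl/6 mice had been stained with the division dye CFSE and transferred into B6D2F1 hosts, which starts a graft-versus-host response. The hosts received vehicle, TCDD or Cl-BBQ, and donor cells were taken from spleen and lymph nodes on day 2 by magnetic beads and flow sorting. The labels give 4 mice per group, aged 10 to 12 weeks, and 3 µg of RNA per labelling reaction. The labels name a labelling kit made for 3′ expression arrays, whereas the probe table belongs to a whole-transcript gene array; which of the entries is wrong could not be settled from the sources used here.

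The deposited values are log2 intensities from robust multi-array average (RMA) processing by the authors, per the labels. The software version, the probe library file and whether RMA ran over these 12 arrays alone are not given in the sources used here. The log2 scale was not stated and was read from the values, which ran from 2.49 to 14.2 with array medians of 7.11 to 7.24. The table held 35556 probe sets. Of these, 21789 carried 1 gene symbol, 1621 carried several and 12146 were not listed in the probe table. Gene names came from that table; the Entrez identifiers of 21698 probe sets were found in the mouse RefSeq annotation (GRCm38.p6), and 0 symbols needed a change. Where a gene had more than 1 probe set, which applied to 999 genes, the probe set with the highest mean over all arrays was kept, leaving 19938 genes. No filter on dim genes was applied. For arrays, the number of arrays limits the precision.

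The 3 groups were fitted together in limma 3.58.1 (R 4.3.3) with 1 coefficient per group, 9 residual degrees of freedom and empirical Bayes moderation with an intensity trend. The comparisons were TCDD against vehicle, Cl-BBQ against vehicle and TCDD against Cl-BBQ, each two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Confidence intervals of log2 differences are at the 95% level and come from the same moderated fit. Fold changes are 2 raised to the difference of the log2 means. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

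Gene lists, 26 in number, were fixed before the data were examined. They cover the AhR battery, Tr1 and co-inhibitory receptors, Treg, Th1, Th2, Th17 and Th22, Tfh, cytotoxic granule, IL-2 and STAT5 signalling, homing and trafficking, naive and quiescence, proliferation, interferon response, glycolysis, cholesterol synthesis, oxidative stress (NRF2), apoptosis, ER stress, early response and dissociation, CD4 T cell identity, CD8 T cell, B and plasma cell, myeloid and dendritic cell, neutrophil and platelet, NK cell, and erythroid genes. The last 7 mark the cells that the sort should keep or remove. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists tested. Camera with an estimated correlation was run beside it, as was fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, and gene calls were also adjusted over the list alone. The CD8 list, with 2 genes, was described without a test. Some intended members had no probe set with a symbol of their own and were not analysed here.

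The genes named were set by a rule fixed in advance. It took Cyp1a1, Cyp1b1, Ahrr, Tiparp and Nqo1 in every comparison. It added, among called genes whose arrays did not overlap between the groups, the 12 with the largest increase and the 10 with the largest decrease. It also took up to 4 members of each list. Called list members beyond those 4, and the genes of the closing section that no list holds, were chosen after their values were seen.

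The similarity of both responses was described by Pearson correlation and covariance of the log2 changes across genes. The shared vehicle arrays raise both measures, so they were set beside 100 simulated sets with unchanged treated groups and beside 6 assignments of the vehicle arrays in pairs to the separate comparisons. The simulated sets drew the deviations of all arrays at random and ignored the pairing by number; for the divided vehicle arrays, the signs of the deviations were turned alike in same-numbered TCDD and Cl-BBQ arrays, in 1176 combinations. The numbers of the replicates are not stated to mark a shared litter, day or batch, and the fit used no block. Whether same-numbered arrays deviate together was checked on their deviations from the group means. For TCDD and Cl-BBQ, all 4 same-numbered pairs correlated over 0.1 (0.606, 0.113, 0.157 and 0.365), so a fit with the number as a block is given beside that comparison where it changes a call. Of the pairs with vehicle arrays, 2 of 4 with TCDD and 0 of 4 with Cl-BBQ did so. Unlike-numbered TCDD and Cl-BBQ arrays ranged from −0.588 (Cl-BBQ 1 with TCDD 4) to 0.419 (Cl-BBQ 2 with TCDD 4). Cl-BBQ 2 thus lay closer to TCDD 4 than to its own number (0.113), so the numbers are not shown to mark pairs. The block was fitted over all 12 arrays, so vehicle arrays also shaped it.

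The calling was tested on simulated data with the number and spread of these arrays. The noise was drawn independently for every gene and array. The real arrays vary together along an axis with 32.2% of the variance within groups, so the rates that follow may not carry over to them. Of 67 genes moved by 0.5 log2, 91% were recovered in each comparison with vehicle and 88.1% in TCDD against Cl-BBQ; at 1 and 2 log2, 100% were recovered. False calls were 6 of 200, 17 of 211 and 12 of 204 in TCDD against vehicle, Cl-BBQ against vehicle and TCDD against Cl-BBQ. A list moved by 0.3 log2 was called in all 3, and camera with the preset correlation also called 1, 2 and 0 lists that had not been moved.

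Alternatives tried were a filter on dim genes, the mean of a gene's probe sets, every probe set on its own, median centring, quantile normalization, a fit of only the groups compared, moderation without a trend, array weights, a replicate block, each replicate left out in turn, a minimum fold change, camera with an estimated correlation, and fry. A covariate for an axis seen within groups, and leaving out the 3 arrays at its low end, were added after seeing the data. Probe sets with several genes or with no entry in the probe table were left out of the gene tests, because they name no single gene.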

Results

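The data were log2 gene expression values of donor CD4+ T cells that had divided at least 2 times by day 2 (48 hr) of a graft-versus-host response, on 4 arrays per group. The hosts had received vehicle on days 0 and 1, TCDD at 15 µg/kg on day 0, or Cl-BBQ at 2 mg/kg on days 0 and 1. TCDD and vehicle hosts thus differed in dosing schedule as well. TCDD is a persistent chlorinated dioxin and Cl-BBQ another compound that binds the aryl hydrocarbon receptor (AhR), a transcription factor activated by ligands. The doses and schedules differed, so the compounds were not compared at a matched dose. Expression was measured for 19938 genes, array medians ran from 7.11 to 7.24, and pairs of arrays correlated at 0.988 to 0.995 across probe sets, which are not independent replicates. Values below are log2 intensities as mean ± SD of 4 arrays, and adjusted p values are from limma.

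The comparison of TCDD with vehicle asks what a single dose to the host changed in the divided donor cells. Cyp1b1, a cytochrome P450 and a known AhR target, rose 11.2-fold, from 6.36 ± 0.14 to 9.85 ± 0.12 (probe set 10453057; adjusted p = 3.6e-05). Genes of receptors that guide T cells to the gut rose next: Ccr9 was 6.75-fold higher (10.33 ± 0.43 against 7.58 ± 0.59; adjusted p = 0.000315) and Gpr15 was 5.64-fold higher (8.96 ± 0.45 against 6.47 ± 0.25; adjusted p = 3.6e-05). The granule protease gene Gzma rose 5.32-fold, from 7.76 ± 0.46 to 10.18 ± 0.25, and Il12rb2, a subunit of the interleukin-12 receptor, rose 3.13-fold (adjusted p = 0.000187). The transcript A530021J07Rik fell the most of the called genes, 2.40-fold, and Itgb1, the integrin β1 chain, was 1.65-fold lower (9.82 ± 0.05 against 10.54 ± 0.15; adjusted p = 0.000667).

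In the AhR battery, 5 of 14 measured genes rose with TCDD, 0 fell and 9 were not called; adjusted over the list alone, 6 rose. Beside Cyp1b1 these were Nqo1, a quinone reductase, at 3.44-fold (8.10 ± 0.20 against 6.32 ± 0.18), Ahrr, a repressor of AhR, at 1.85-fold, Tiparp, an ADP-ribosyltransferase, at 1.77-fold, and Cyp1a1 at 1.66-fold. Ahrr and Cyp1a1 were dim enough to be removed by the filter tried as an alternative. Camera called the list (adjusted p = 2.94e-09; adjusted p = 0.093 with an estimated correlation), and fry gave an adjusted p of 0.00199.

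Among Tr1 and co-inhibitory receptor genes, 6 of 24 rose, 1 fell and 17 were not called; adjusted over the list alone, 7 rose and 1 fell. Havcr2, which encodes the inhibitory receptor TIM-3, was 2.86-fold higher (adjusted p = 0.0113), Itga2, an integrin chain, 2.59-fold, Prdm1, the transcription factor Blimp-1, 2.33-fold, and the cytokine gene Il10 2.11-fold (adjusted p = 0.00797). Ctla4, an inhibitory receptor, rose 1.26-fold, Nfil3 also rose and Cd226, a co-stimulatory receptor, fell. Camera called this list (adjusted p = 1.22e-05; adjusted p = 0.448 with an estimated correlation), and fry did not (adjusted p = 0.134).

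Genes of T helper subsets moved in part. In the Th1 list 5 of 19 rose (Il12rb2, Il18rap, Runx3, Cxcr6 and Id2) and 2 fell (Eomes and Lta); adjusted over the list alone, 7 rose and 3 fell. The chemokine receptor gene Cxcr6 was 2.51-fold higher, Il18rap, a subunit of the interleukin-18 receptor, 1.61-fold higher and Eomes, a T-box transcription factor, 1.56-fold lower. In the Th2 list 2 of 12 rose, namely Ccr4, a chemokine receptor, at 2.84-fold and Gata3, a transcription factor, at 1.32-fold, with 3 higher and 1 lower adjusted over the list alone. In the Treg list Itgae, the integrin chain CD103, and the cytokine gene Tgfb3 rose and the other 17 of 19 were not called; adjusted over the list alone, 2 rose and 3 fell. No member was called in the Th17 and Th22 list (11 measured) or the Tfh list (11 measured), where adjusting over the list alone gave 0 calls and 1 higher with 1 lower. Camera called none of these 5 lists, with adjusted p from 0.0773 for Th2 to 0.913 for Treg, whereas fry called Th2 (adjusted p = 0.00802).

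Of 18 homing and trafficking genes, 4 rose (Ccr9, Gpr15, Ccr2 and Selplg), 1 fell (Itgb1) and 13 were not called; adjusted over the list alone, 6 rose and 3 fell, and camera gave an adjusted p of 0.0773. Ccr2, a chemokine receptor, was 2.53-fold higher. Of 20 cytotoxic granule genes, Gzma, Gzmb at 3.29-fold (adjusted p = 0.00115) and Prf1, which encodes perforin, at 1.37-fold rose; adjusted over the list alone these were also 3, and camera gave an adjusted p of 0.188. Of 18 IL-2 and STAT5 genes, Pim1, a kinase, rose 1.46-fold, Socs3, a feedback inhibitor, rose 1.37-fold and the cytokine gene Il2 fell 1.40-fold (adjusted p = 0.0415); adjusted over the list alone 4 rose and 4 fell, and camera gave an adjusted p of 0.983. Dapl1 fell 1.84-fold as the only called gene of 17 in the naive and quiescence list, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.672). Gbp3, an interferon-induced GTPase, rose 1.33-fold as the only called gene of 19 in the interferon list, with 3 higher adjusted over the list alone (camera adjusted p = 0.0871).

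Other large increases with TCDD were those of Myo1f, a myosin, at 3.64-fold, Cysltr1, a leukotriene receptor, at 3.20-fold, and Ifitm3, an interferon-induced membrane protein, at 2.69-fold. Large decreases included AB124611 at 2.18-fold, Gstp3, a glutathione transferase, at 1.90-fold, Tarsl2, a tRNA synthetase gene, at 1.87-fold, Nrn1 at 1.82-fold and Plxnc1, a semaphorin receptor, at 1.79-fold.

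No member was called with TCDD in the lists of proliferation (28 measured), glycolysis (16), cholesterol synthesis (15), NRF2 (13), apoptosis (15), ER stress (18) or early response genes (16), and camera gave adjusted p from 0.188 to 0.983. Adjusted over the list alone, NRF2 and early response genes had 1 higher each and apoptosis 2 lower. Among marker lists, 0 of 13 CD4 T cell identity genes, 0 of 2 CD8 genes, 0 of 12 neutrophil and platelet genes and 0 of 5 erythroid genes were called, and adjusting over the list alone added none. In the B and plasma cell list, Cd22, a lectin known from B cells, fell 1.94-fold and Bank1, a B cell scaffold protein, fell 1.40-fold (adjusted p = 0.0392), while the other 11 of 13 were not called. Cd74, the invariant chain of MHC class II, fell 1.35-fold as the only called gene of 20 in the myeloid and dendritic list. In the NK list of 7, Gzma rose and Eomes fell. Adjusted over the list alone, the counts were 2 lower for B cells, 1 lower for myeloid cells, and 1 higher with 2 lower for NK cells. Camera gave adjusted p of 0.408 to 0.793 for the marker lists tested. The median, mean and test of a list differed in sign for naive, apoptosis, early response, myeloid and NK genes.

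With TCDD 247 genes were called, 174 higher and 73 lower, against 1733 at an unadjusted p under 0.05; 33 changed by at least 2-fold. The groups did not overlap in 244 of the called genes, which were picked for their difference; over all genes this held for 5.8%, where chance gives 2.86%. The count ranged from 150 without TCDD replicate 3 to 227 with each replicate left out in turn, and was 160 after median centring and 391 with array weights. Of 45 called genes set by the naming rule, 10 lost their call in some of these 8 fits: Il2 in 7, Bank1, Cd74, Gbp3 and Prf1 in 6, Gata3 and Nrn1 in 5, Eomes in 4, and Havcr2 and Plxnc1 in 1, without TCDD replicate 3. Of the list members named beyond the rule, Cd226 and Lta lost it in 7, Id2 in 6, Nfil3 in 4 and Selplg in 3. Camera called 2 lists and none with an estimated correlation; it called 7 without TCDD replicate 1 and 5, 8 and 5 without vehicle replicates 1, 2 and 4, and at least 2 in 29 of the 35 divisions of the 8 arrays into 4 and 4.

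**Figure D1:**
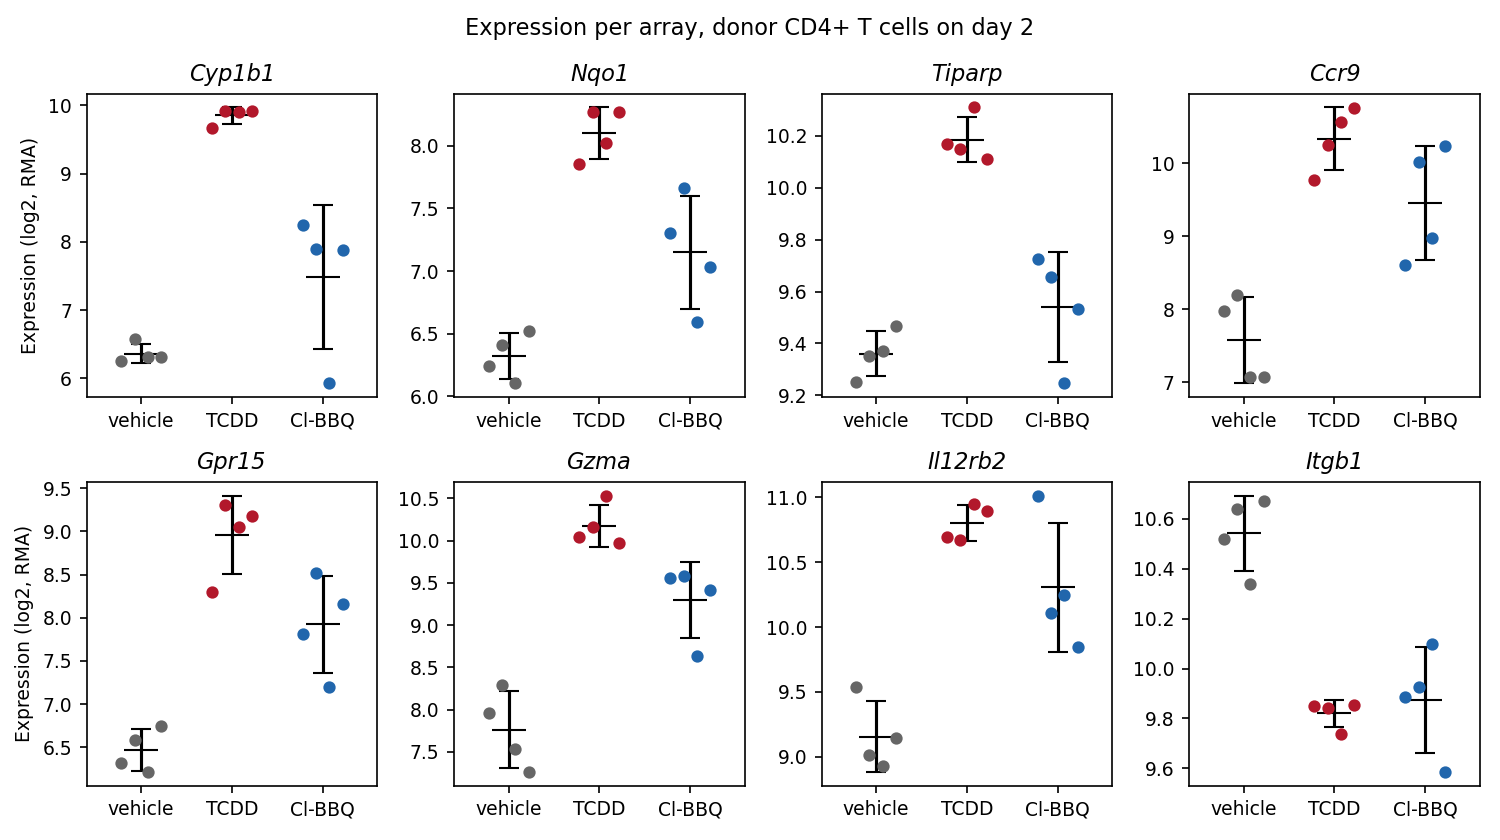
Log2 expression of 8 genes on the 12 arrays, with a panel and a vertical scale for each gene; points are arrays in replicate order from left to right, and bars are the mean ± SD of 4 arrays. Cyp1b1 on the Cl-BBQ array of replicate 3 lies at 5.93, below the other Cl-BBQ arrays (7.89 to 8.24).

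The comparison of Cl-BBQ with vehicle asks the same of 2 doses of the other compound. Ccr9 rose 3.68-fold, to 9.46 ± 0.79 (adjusted p = 0.0362), Gzma 2.89-fold, to 9.30 ± 0.45 (adjusted p = 0.0135), and Gpr15 2.75-fold (adjusted p = 0.0243). Myo1f was higher by 1.38 log2 (8.70 ± 0.20 against 7.32 ± 0.38; adjusted p = 0.0068), Gzmb 2.52-fold and Il12rb2 2.22-fold (adjusted p = 0.0243). The genes that fell included Ctnnal1, a relative of the α-catenins, at 1.85-fold (7.61 ± 0.27 against 8.49 ± 0.19; adjusted p = 0.00889), Cd86, a co-stimulatory ligand, at 1.65-fold and Itgb1 at 1.59-fold (adjusted p = 0.0135). Further increases were those of Cd7 at 1.96-fold, Cldnd1 at 1.89-fold, Cysltr1 at 1.84-fold and Emp1 at 1.80-fold, and further decreases those of Tarsl2 at 1.68-fold, Sema4a, a semaphorin, at 1.62-fold and Gjb2, a connexin, at 1.48-fold.

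No AhR battery gene was called with Cl-BBQ over all genes, and 3 were higher adjusted over the list alone. Cyp1b1 was at 7.49 ± 1.05, 2.18 times vehicle (adjusted p = 0.298), Nqo1 at 1.78 times (adjusted p = 0.0735), Cyp1a1 at 1.16 times (adjusted p = 0.587), Ahrr at 1.31 times (adjusted p = 0.129) and Tiparp at 1.13 times (adjusted p = 0.67). The Cl-BBQ array of replicate 3 lay at 0.0999 of the way from vehicle to TCDD over the 5 AhR battery genes called with TCDD, where the other Cl-BBQ arrays lay at 0.399 to 0.539; in Cyp1b1 it lay at 5.93, below all vehicle arrays (6.25 to 6.57). Without it Cyp1b1 was called (log2 change 1.65; adjusted p = 3.5e-06), and so were Nqo1 (adjusted p = 0.00721) and Ahrr (log2 change 0.47; adjusted p = 0.0492). Camera called the list in the higher direction (adjusted p = 0.0015; adjusted p = 0.587 with an estimated correlation), and fry did not (adjusted p = 0.234).

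The 28 proliferation genes held 0 called members with Cl-BBQ, also adjusted over the list alone, with a median log2 change of −0.06. Camera called this list lower (adjusted p = 0.0015; adjusted p = 0.895 with an estimated correlation), fry did not (adjusted p = 0.793), and camera did not call it without Cl-BBQ replicate 4 or without vehicle replicate 4.

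In the other lists the called genes with Cl-BBQ were Itga2 of 24 Tr1 genes (1.84-fold higher), Tgfb3 of 19 Treg genes (1.59-fold higher), Il12rb2 of 19 Th1 genes, Gzma and Gzmb of 20 cytotoxic granule genes, Ccr9 and Gpr15 (higher) and Itgb1 (lower) of 18 homing genes, and Gzma of 7 NK genes. Adjusted over the list alone, the counts were 3 higher for Tr1, 1 higher and 2 lower for Treg, 5 higher and 2 lower for Th1, 3 higher for cytotoxic granule genes, 5 higher and 2 lower for homing and 1 higher with 1 lower for NK genes. Camera gave adjusted p of 0.0582 for cytotoxic granule, 0.0624 for Tr1 and 0.0999 for homing genes. No Th2, IL-2 and STAT5, naive or B cell gene was called over all genes, and adjusting over the list alone gave 2 higher and 1 lower, 3 higher and 1 lower, 1 higher and 2 lower, and 2 lower. The remaining 14 lists, among them glycolysis, ER stress, CD4 T cell identity and myeloid genes, had 0 calls either way. The median, mean and test differed in sign for IL-2 and STAT5, naive, glycolysis, apoptosis, early response, B cell, myeloid and NK genes.

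With Cl-BBQ 39 genes were called, 29 higher and 10 lower, against 1577 at an unadjusted p under 0.05; 6 changed by at least 2-fold. The groups overlapped in none of the 39, which were picked for their difference; over all genes this held for 3.85%, where chance gives 2.86%. The count ranged from 3 to 61 with each replicate left out in turn: 61, 3 and 16 without Cl-BBQ replicates 1, 2 and 4, and 9 and 4 without vehicle replicates 1 and 4; it was 0 with every probe set tested on its own, 8 after median centring, 11 from a fit of the 2 groups, 18 without an intensity trend and 71 after quantile normalization. Of 23 called genes set by the naming rule, 20 lost their call without some replicate, among them Ccr9, Gpr15 and Gzmb in 5 of the 8 fits, Il12rb2 in 4, and Gzma and Itgb1 in 2, without Cl-BBQ replicate 2 or vehicle replicate 4; Myo1f, Cldnd1 and Ctnnal1 kept theirs. Camera called 2 lists, none with an estimated correlation or fry, and 7 and 4 without Cl-BBQ replicates 1 and 2, 7 and 4 without vehicle replicates 2 and 4, and at least 2 in 33 of the 35 divisions of the 8 arrays.

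The comparison of TCDD with Cl-BBQ tests the difference between the compounds at their own doses and schedules. Cyp1b1 was 5.16-fold higher with TCDD (log2 difference 2.37, interval 1.66 to 3.08; adjusted p = 0.0356). Tiparp was 1.56-fold higher (adjusted p = 0.0356), and Kit, the receptor of stem cell factor, was 1.60-fold higher (7.84 ± 0.17 against 7.16 ± 0.21; adjusted p = 0.039).

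Other AhR battery genes did not pass the test of the difference over all genes, but 3 passed it under alternatives. Nqo1 passed with the replicate number as a block (adjusted p = 0.0176), with array weights (adjusted p = 0.022) and without Cl-BBQ replicate 2 (adjusted p = 0.0313), Ahrr with array weights (adjusted p = 0.0488), and Cyp1a1 with array weights, without Cl-BBQ replicate 1 and without 3 arrays at an end of the axis within groups (highest adjusted p = 0.0165). The log2 difference was 0.95 for Nqo1 (interval 0.59 to 1.32; adjusted p = 0.21), 0.51 for Cyp1a1 (interval 0.31 to 0.71; adjusted p = 0.21) and 0.50 for Ahrr (interval 0.30 to 0.70; adjusted p = 0.238). Adjusted over the list alone, 5 of the 14 were higher with TCDD and 0 lower. Camera called the AhR battery (adjusted p = 2.96e-08; adjusted p = 0.0649 with an estimated correlation), and fry gave an adjusted p of 0.048.

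The receptor and granule genes that rose with both compounds were not shown to differ between them without a block; Gpr15 passed with the replicate block (adjusted p = 0.0348). The log2 difference was 1.04 for Gpr15 (interval 0.53 to 1.55; adjusted p = 0.503), 0.88 for Gzma (interval 0.42 to 1.35; adjusted p = 0.678), 0.88 for Ccr9 (interval 0.16 to 1.59), 0.50 for Il12rb2 (interval 0.10 to 0.90) and 0.39 for Gzmb (interval −0.13 to 0.91). For genes that fell with both, the difference was −0.05 for Itgb1 (interval −0.26 to 0.15) and −0.03 for Ctnnal1 (interval −0.28 to 0.22). An interval that excludes 0 here is that of a single gene, without correction for the number of genes.

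Camera called 5 further lists higher with TCDD than with Cl-BBQ, none with a called gene. NRF2 genes (median log2 difference 0.05) had an adjusted p of 0.000173, and an adjusted p = 0.0408 with an estimated correlation; fry gave an adjusted p of 0.048. Cholesterol synthesis genes had a median log2 difference of 0.11 (adjusted p = 0.359 with an estimated correlation), Tr1 genes of 0.04 (adjusted p = 0.359 with an estimated correlation), Treg genes of 0.05 (adjusted p = 0.383 with an estimated correlation) and proliferation genes of 0.06 (adjusted p = 0.806 with an estimated correlation). Fry called none of these 4, and camera lost Tr1 and Treg without Cl-BBQ replicate 1 (adjusted p = 0.0727 and 0.192) and without 3 arrays at an end of the axis within groups, Treg also without TCDD replicate 4, and proliferation without Cl-BBQ replicate 4 (adjusted p = 0.572) and with array weights (adjusted p = 0.0985). Adjusted over the list alone, Treg had 2 higher, Th2, cytotoxic granule, homing, interferon and NK genes 1 higher each, and the other lists beside the AhR battery 0. The median, mean and test differed in sign for cytotoxic granule, early response, NK and erythroid genes.

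Between the compounds 3 genes were called, all higher with TCDD, against 596 at an unadjusted p under 0.05. The groups did not overlap in these 3, which were picked for their difference; over all genes this held for 2.04%, where chance gives 2.86%. With the replicate number as a block, 5 genes were called, Nqo1 (adjusted p = 0.0176) and Gpr15 (adjusted p = 0.0348) being added. The count ranged from 0 to 7 with each replicate left out in turn: 7, 1 and 0 without Cl-BBQ replicates 1, 3 and 4, and 0 without any 1 of the 4 TCDD replicates; the gene left without Cl-BBQ replicate 3 was Cyp1b1. It was 0 with every probe set tested on its own, after quantile normalization, in a fit of the 2 groups and without an intensity trend, and 9 with array weights; at least 3 genes were called in 2 of the 35 divisions of the 8 arrays, and at least 6 lists in 17.

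The changes with both compounds were also compared across genes, which are not independent replicates. All 39 genes called with Cl-BBQ were among the 247 called with TCDD: 29 rose and 10 fell with both, where independence would give 0.253 and 0.0366 genes. The shared vehicle arrays raise this overlap, and the pairing of TCDD and Cl-BBQ arrays by number can raise it too. The log2 changes correlated at r = 0.779 over all genes, against a mean of 0.513 (range −0.316 to 0.928) in simulated sets with unchanged treated groups. With the vehicle arrays divided between the comparisons, r was 0.42 (range 0.279 to 0.475 over 6 assignments), against a mean of 0.193 (range −0.395 to 0.847) in sets without a change that kept same-numbered TCDD and Cl-BBQ arrays together. Neither r lay outside its range, so neither shows that the responses are alike over all genes. All 247 genes called with TCDD had the same sign with Cl-BBQ, against a mean of 88.4% (range 2.02 to 100) among the 247 genes of smallest p picked in each simulated set, so a shared sign of all is not evidence of a shared response. For 100 genes chosen on part of the TCDD and vehicle arrays, Cl-BBQ was compared with the vehicle arrays left out. Its mean change in the TCDD direction was 0.431 to 0.593 log2 over 36 choices. That argues against the shared vehicle arrays as the whole source of a shared direction at these genes. The pairing by number was not removed there. Of the 247, 243 had the smaller change with Cl-BBQ, with a median ratio of the log2 changes of 0.669 (quartiles 0.558 and 0.762). These genes were picked by their TCDD change, which lowers the ratio; at the 39 genes called with Cl-BBQ, it was 0.724, and 38 had the smaller change with Cl-BBQ.

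**Figure D2:**
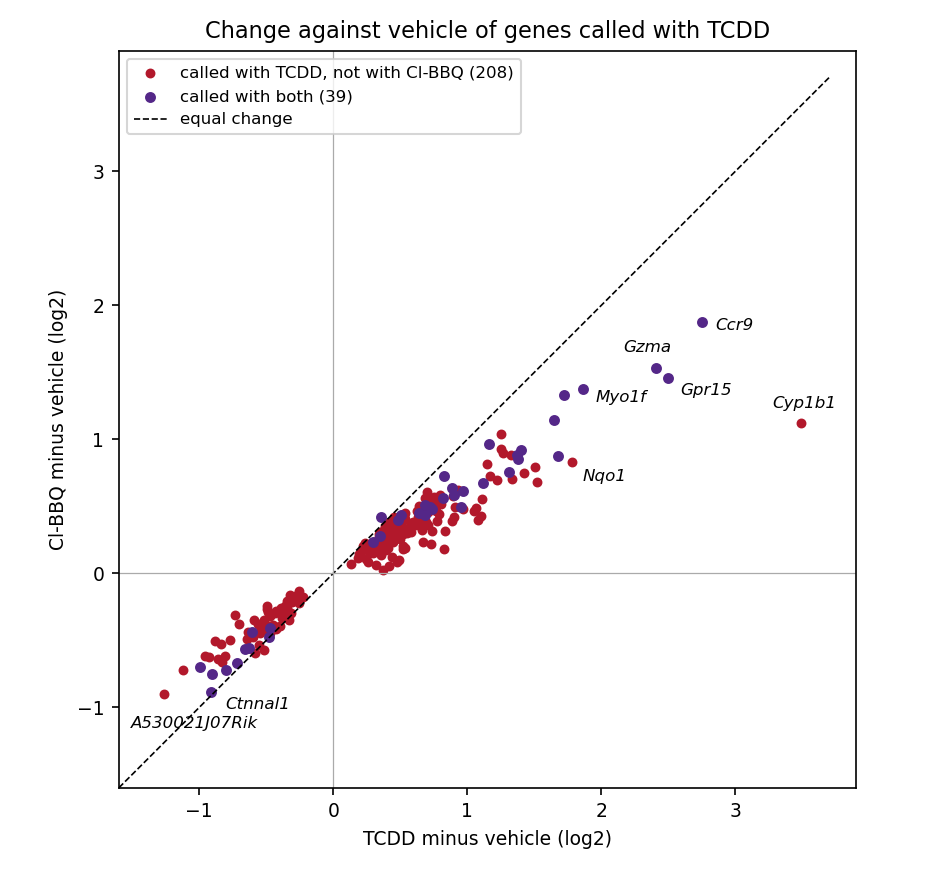
Log2 change with Cl-BBQ (vertical) against log2 change with TCDD (horizontal), both against vehicle, for the 247 genes called with TCDD; purple points are the 39 genes called with both compounds, red points those called with TCDD and not with Cl-BBQ, and the dashed line marks equal changes. Of the 247 genes, 243 changed less with Cl-BBQ.

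**Figure D3:**
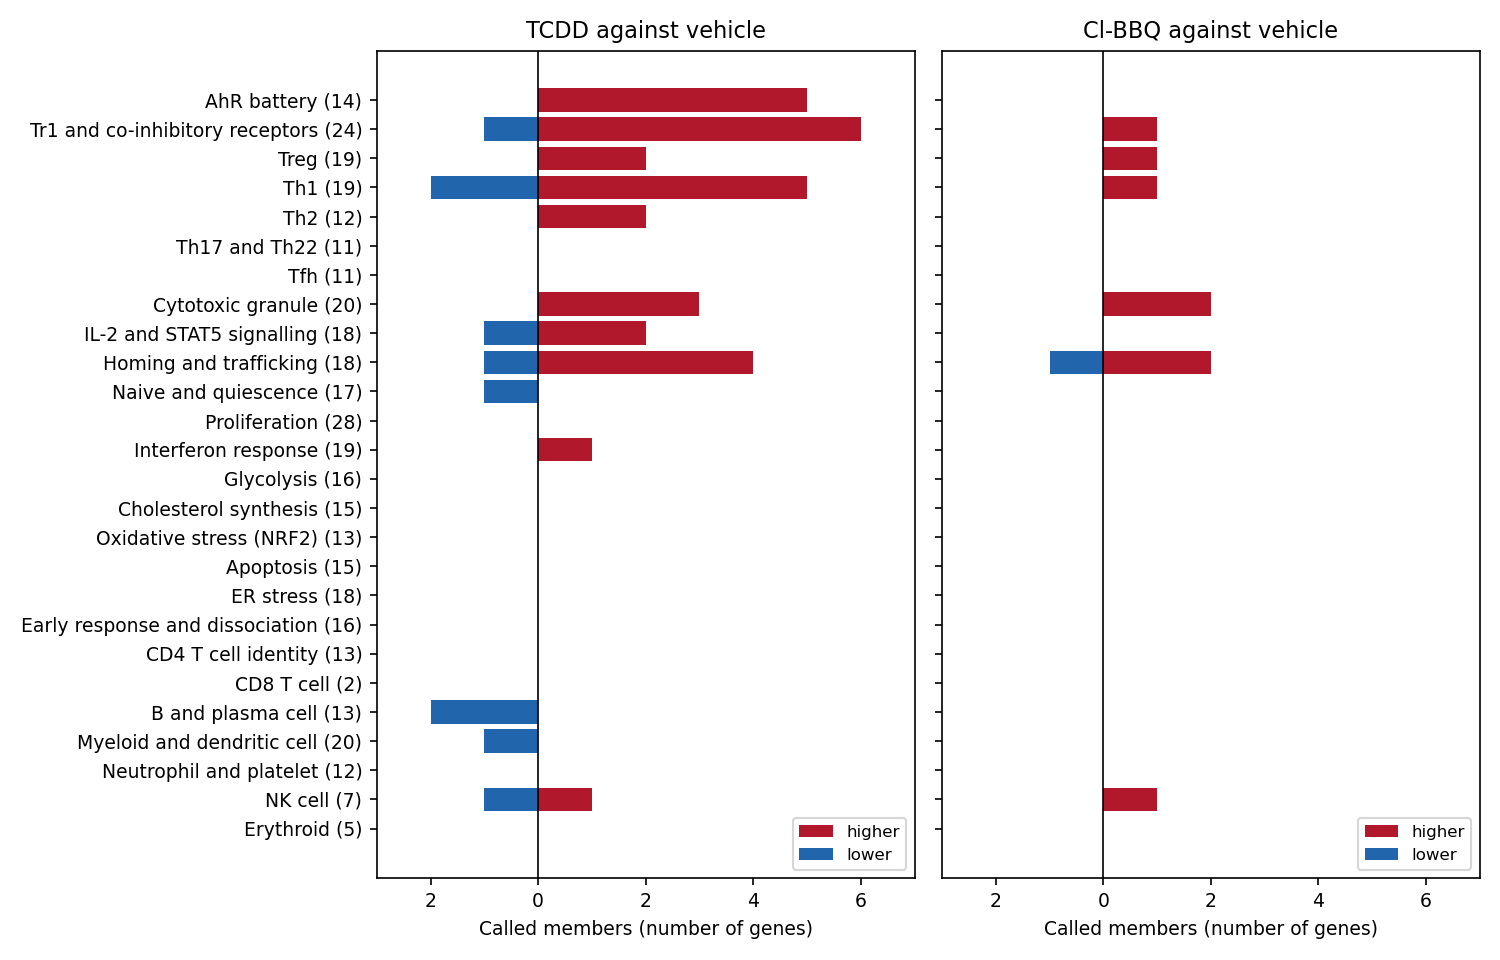
Number of called genes per fixed list in each comparison with vehicle, higher to the right and lower to the left, with the number of measured members in brackets. With TCDD the AhR battery held 5 of 14 higher and proliferation genes 0 of 28.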

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

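The tests of the 3 patterns weighed here were chosen only after the results were seen. Values stand apart where the gap of the highest or lowest array to the nearest of its group divided by the group's range exceeds the 95% critical value of Dixon's test. This held for 37 of 666 groups of 4 values (5.56%), and chance gives about 1 in 20; Cl-BBQ replicate 1 held 9 of the 37.

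The AhR battery stood apart in Cl-BBQ replicate 3. Its list score was −0.29 against 0.01 to 0.07 on the other Cl-BBQ arrays, and Cyp1b1 was at 5.93 against 7.89 to 8.24, below all vehicle arrays (6.25 to 6.57); Tiparp (9.25) also lay below them, Cyp1a1 (6.43) among them, and Nqo1 (6.59) and Ahrr (5.95) above them. Over the 242 other genes called with TCDD, this array lay at 0.542 of the way from vehicle to TCDD, above every vehicle array (−0.111 to 0.115). These genes were picked on the same vehicle and TCDD arrays. That keeps the vehicle arrays near the vehicle end and can draw any other array towards TCDD. The position therefore cannot exclude a mislabelled vehicle array or a host without ligand. The residual SD of this array, 0.167, was not the highest of the Cl-BBQ arrays (0.178 to 0.213 on the others). That SD includes the axis seen within groups, on which this array lay at −13.6 and Cl-BBQ replicates 1, 2 and 4 at −33.3, 19.8 and 27.1. The ranking may thus reflect the axis, so it cannot exclude a noisy array. Receptor signalling that had ended while later responses persisted is neither supported nor excluded: the position over the AhR genes, 0.0999, lay above the highest vehicle array (0.0785) rather than at or under it, and 0.542 lay below the other Cl-BBQ arrays (0.619 to 0.74) by less than their spread (a gap of 0.387 of the range); a lower exposure of this host is open too and was not tested.

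Fewer genes were called with Cl-BBQ (39) than with TCDD (247). Larger spread between the Cl-BBQ arrays would leave the changes alike in size, but over genes chosen on part of the TCDD and vehicle arrays and measured on the rest, the median ratio of Cl-BBQ to TCDD change was 0.656 (0.549 to 0.747 over 36 choices), and 0 choices reached 1. This argues against spread as the whole reason. The 3 groups also shared 1 estimate of spread in the fit, so a gene had the same standard error in both comparisons with vehicle (0.158 for Cd22). Larger spread of the Cl-BBQ arrays therefore did not give their comparison a larger error term than that of TCDD. The highest ratio of 0.747 is consistent with a smaller response at the dose and schedule of Cl-BBQ used. Compound, dose and schedule changed together in this design, so their parts cannot be told apart.

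Cd22, Bank1 and Cd74, known from B cells and antigen-presenting cells, were lower with TCDD, by log2 changes of −0.95, −0.48 and −0.43, although the cells had been sorted on CD4. The median change of the B cell transcripts Cd79a, Cd79b, Ms4a1 and Ighm was −0.0808 (−0.15 to 0.23). In vehicle Ms4a1 (5.07) and Cd79a (6.52) lay below the array medians, where a fall may not show, but Cd79b (7.54) and Ighm (7.53) lay above them and near Bank1 (7.61), and changed by 0.23 and −0.04 (standard errors 0.0928 and 0.0888). This argues against fewer B cells as the whole reason for the lower values. Cd86, Cd83 and Irf8, which antigen-presenting cells also express, fell too (by 0.80, 0.53 and 0.54), but were picked after their values were seen. Irf8 lost its call in 7 of the 8 fits with a replicate left out. The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 changed by −0.13, 0.04 and 0.04 and were not called. In vehicle, H2-Aa and H2-Ab1 lay below the array medians, and H2-Eb1 (7.195) lay near Cd74 (7.252). Fewer antigen-presenting cells of another kind and a change within the T cells stay open, and neither was tested.

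Other values stood apart from the 3 remaining arrays of their group. On Cl-BBQ replicate 1 these were A530021J07Rik at 6.59, Calr at 12.41, Dapl1 at 10.98, Gstp3 at 11.09, Il13 at 7.98, Il17f at 7.20, Il2 at 6.79, Itga2b at 7.38 and Pdia4 at 10.68. On Cl-BBQ replicate 2 it was the Th2 list score at 0.0561. On Cl-BBQ replicate 3 they were Cd22 at 7.77, Gzma at 8.63 and the NK list score at −0.24. On Cl-BBQ replicate 4 they were Birc5 at 12.32, Gimap4 at 12.71, Il10 at 8.15 and Nfil3 at 9. Among TCDD arrays, replicate 1 stood apart in Cyp1b1 at 9.68, Il13 at 7.88 and the homing list score at 0.0205, replicate 2 in Msmo1 at 10.81, replicate 3 in Itgb1 at 9.74 and S100a9 at 6.25, and replicate 4 in Ebi3 at 7.27. Among vehicle arrays, replicate 1 stood apart in the Th17 and Th22 list score at −0.10, and replicate 2 in Cd8a at 8.47 (6.96 to 7.03 on the others), Hsp90b1 at 12.83 and Klf3 at 11.01. Vehicle replicate 3 stood apart in Alas2 at 7.46, Armcx4 at 7.61, Ngp at 5.34 and the erythroid list score at 0.11, and vehicle replicate 4 in Il2 at 7.68, Satb1 at 12.40 and Slc4a1 at 7.23.

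Probe sets that no gene test used also changed. With every probe set tested on its own, 210 were called in TCDD against vehicle, of which 32 had no gene in the probe table and 5 had several.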

How the results depend on the processing

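The covariate for the axis within groups and the omission of the 3 arrays at its low end were chosen after the data were seen; the other alternatives were planned. Of 8408 values of named genes and lists under the alternatives, 7677 kept their direction and their side of the threshold, 421 no longer passed, 151 newly passed, 159 that had not passed changed sign, and 0 that had passed reversed. For TCDD against vehicle (247 genes, 2 lists), the genes were 160 after median centring, 391 with array weights, 33 at a minimum of 2-fold, 535 with the axis covariate and 150 (without TCDD replicate 3) to 227 with a replicate left out. The lists were 0 with an estimated correlation, 6 with the dim filter and 2 to 8 with a replicate left out (7 without TCDD 1; 5, 8 and 5 without vehicle 1, 2 and 4). For Cl-BBQ against vehicle (39 genes, 2 lists), the genes were 0 with every probe set on its own, 8 after centring, 71 after quantile normalization, 11 from the compared groups alone, 18 without trend, 6 at 2-fold, 213 with the covariate and 3 to 61 with a replicate left out (61, 3 and 16 without Cl-BBQ 1, 2 and 4; 9 and 4 without vehicle 1 and 4). The lists were 0 with an estimated correlation, 0 with fry, 5 with the dim filter, 4 after centring, 5 with weights, 7 without the 3 arrays, and 2 to 7 with a replicate left out (7 and 4 without Cl-BBQ 1 and 2; 7 and 4 without vehicle 2 and 4). For TCDD against Cl-BBQ (3 genes, 6 lists), the genes were 0 with every probe set on its own, after quantile normalization, from the compared groups alone and without trend, 9 with weights, 5 without the 3 arrays, 1 at 2-fold and 0 to 7 with a replicate left out (7, 1 and 0 without Cl-BBQ 1, 3 and 4; 0 without any TCDD replicate). The lists were 1 with an estimated correlation and 2 with fry. The replicate block gave 397 genes for TCDD against vehicle, 111 genes and 4 lists for Cl-BBQ against vehicle, and 5 genes for TCDD against Cl-BBQ. Same-numbered arrays did not pair with vehicle (r over 0.1 in 2 of 4 pairs with TCDD and 0 of 4 with Cl-BBQ), and 0 of 12 arrays were closest to their own number in both other groups. Between TCDD and Cl-BBQ all 4 pairs were over 0.1, and beside Nqo1 and Gpr15 the block changed no call of a named gene or list there. The correlation of both responses was 0.42 with divided vehicle arrays, 0.84 with the dim filter and 0.692 to 0.81 with a replicate left out. A minimum fold lowers a count by construction. The axis covariate was built from the deviations of these same arrays from their group means. It therefore left the log2 changes as they were and took variance from the residual, which favours more calls. The 535 and 213 genes are thus no support for further changes, and for TCDD against Cl-BBQ the count stayed at 3. The cause was not tested for the other alternatives. Signal over background was not used here. The dim filter kept 63 of the 66 named genes called with TCDD, and removed Cyp1a1, Ahrr and Cd74, whose calls were thus not tested under it. What dim signals limit was not analysed further here.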

Other observations

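The gene groups of the next paragraph were chosen only after their values were seen, and the divisions of the arrays were planned before.

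Gene families, sorted by symbol, held genes that rose with TCDD and are in none of the fixed lists. Of 13 measured S100a genes, which encode small calcium-binding proteins, 3 rose: S100a6 at 2.41-fold (11.69 ± 0.39 against 10.43 ± 0.47 log2, mean ± SD of 4 arrays; limma adjusted p = 0.00484), S100a11 at 1.55-fold and S100a10 at 1.39-fold. Of 8 galectin genes, Lgals3 rose 1.58-fold (limma adjusted p = 0.00135) and Lgals1 1.21-fold, and of 7 Ifitm genes, Ifitm3 and Ifitm2 rose, the latter 1.59-fold. Among 8 Gimap genes, Gimap7, a GTPase of lymphocytes, rose with TCDD (1.40-fold) and with Cl-BBQ (1.32-fold). Of 12 annexins only Anxa6 was called, with a log2 change of 0.04 to 0.22 and a call lost in 10 of 18 alternatives, among them the mean of its probe sets. Gbp7 rose 1.28-fold among 8 guanylate-binding protein genes, of which Gbp3 is in the interferon list, and lost its call in 7 of 18. Of 16 chemokine receptor genes 4 rose, each in a fixed list. In these 7 families 0 genes were lower with TCDD, and 2 were called with Cl-BBQ, Gimap7 and Ccr9. With each replicate left out in turn, Anxa6 and Gbp7 lost their call with TCDD in 4 of 8 fits, and Gimap7 lost its call with Cl-BBQ in 5 of 8. Among genes that fell with TCDD, Cd86 was 1.74-fold lower and Cd83, a marker of activated antigen-presenting cells, 1.44-fold lower, in the comparison where Cd22, Bank1 and Cd74 fell as well. These were picked singly and stand for no tested group. Of genes for receptors of CD86, Cd28 was not called and Ctla4 rose.

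The 8 arrays of each comparison can be divided into 4 and 4 in 35 ways. For TCDD against vehicle the real division gave 247 genes and the highest other 0, and for Cl-BBQ against vehicle 39 and 3. So 1 of 35 divisions in each gave a count as large, a share under 0.05. That is the smallest share 35 divisions can give, so chance is made less likely for both gene counts but is not excluded. The other divisions mix treated with vehicle arrays, which adds any real change to their spread and lowers their counts. For TCDD against Cl-BBQ 2 of 35 gave at least the 3 genes found, and chance is not excluded. Of the 8 divisions that part every same-numbered pair, the real one gave 3 genes and the highest other 0; these are too few for a share under 0.05, and the others keep at least 1 pair together. The highest other, with 932 genes, set replicates 1 and 3 of both groups against replicates 2 and 4, which points to a structure of the samples. That division follows the axis that holds 32.2% of the variance within groups, with replicates 1 and 3 at −33.3 and −13.6 (Cl-BBQ) and −10.1 and −16.8 (TCDD), and replicates 2 and 4 at 7.07 to 27.1. For the counts of lists, 29 of 35 (real 2, highest other 12), 33 of 35 (real 2, highest other 10) and 17 of 35 (real 6, highest other 12) were as large, so chance is not excluded for lists called with the preset correlation.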
